A study of Mus musculus with 19 samples.

How the data were processed

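Raw counts per gene symbol were taken from the 2 deposited count tables, 1 per cell type, each with 24421 symbols; per the file headers the columns are the 19 libraries, and the unit is the count. The 2 deposited normalized tables hold log2 values of the authors for 11059 genes in cDC1 and 11441 in cDC2. These are the genes above 1 CPM in at least 3 libraries. The deposited log2 values equal the log2 of CPM (counts per 1e6 counts) with 0.5 added to each count, plus 1 offset per library of −0.0768 to 0.124 in cDC1 and −0.0312 to 0.0706 in cDC2. The submitters' processing notes name FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0, SAMtools 0.1.19, limma 3.42.2 and the mm10 genome. The program that counted reads and its annotation are not given in the sources used here.

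Per the labels, each library was sorted from 5000 to 50000 cells, and groups were formed by cell type and genotype as labelled. The labels state no batch, sex or pairing. Coordinates are GRCm38 from GENCODE M21, in which 23334 of the symbols were matched.

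Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the 3 genotypes of a cell type were fitted together. Comparisons used the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F, an approximation. CPM values are means with SD, over the counts of the tested genes scaled by TMM within a cell type. For the WT cells of both types they were scaled over all 19 libraries, so they differ slightly, and for sort markers and pancreatic transcripts they are unscaled, over all counts. Differences of effect between the cell types were tested as an interaction in a fit of all 19 libraries. Against groups with 0 counts, folds were computed from a floor of 3 counts over the group.

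Lists of genes, 32 in number, were fixed before the data were examined, as were the groups, the tests, the thresholds and the alternatives except where stated. Lists with at least 5 tested members were tested by camera (limma 3.58.1) at the preset correlation of 0.01 on log2 CPM with a prior count of 2. The alternatives were camera with the correlation estimated from the residuals, and fry. Counts of members were also adjusted over the list alone.

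Genes were named by a rule fixed before the data were examined. Ern1 and Xbp1 were named everywhere. In each comparison the 6 raised and 6 lowered genes with the largest fold changes were eligible, among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, without predicted genes and receptor segments. Each list with a called member contributed up to 4 members with the smallest adjusted p, with the 2 most abundant added for lists of other cells, and each interaction the 10 smallest. Not all eligible genes are printed, and some results withheld for evaluation are not reported here. Ccr7 in 1 comparison, Hspa5 in cDC1 Xbp1 KO against WT, Gm2a, Plcb1, Adamdec1 and Mettl17 fall outside the rule.

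Overlaps of calls that share WT or knockout libraries were set against 20 simulations without effects that kept the shared libraries. Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom, limma on the deposited log2 values, no filter and a stricter filter on counts, a replicate block, fits of the compared groups alone, WT libraries of each name, and each library left out. A group left with 1 library was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

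The pipeline was tested on simulated counts with 200 changed genes, 100 at each fold. In cDC1 it recovered 58% of 2-fold and 80% of 4-fold changes for Xbp1 KO against WT (11134 genes run, 4 unchanged genes called), 54% and 89% for Xbp1-Ire1 KO against WT (11131 genes, 8) and 62% and 85% between the knockouts (11152 genes, 9). In cDC2 it recovered 48% and 93% (11481 genes, 10), 64% and 86% (11474 genes, 14) and 57% and 89% (11487 genes, 7) in the same order. For the interactions it recovered 26% and 68% (11923 genes, 7), 34% and 73% (11961 genes, 5) and 28% and 66% (11934 genes, 5). Of 20 simulated lists of 25 members, the 1 changed 1.5-fold was called in each of the 6 comparisons, and 0 others were. Genes were drawn independently there, so this cannot show how often real lists, whose members may vary together, are called without an effect. Splits of the real libraries that mixed the groups also called lists, as given below.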

Results

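RNA was sequenced from conventional dendritic cells sorted from the spleen of C57BL6 mice. The cDC1 subset takes up dying cells and presents antigen to CD8 T cells, and the cDC2 subset presents mainly to CD4 T cells. Each subset came from wild type mice (WT), from mice lacking Xbp1 (Xbp1 KO) and from mice lacking both Xbp1 and the gene of its activating enzyme IRE1 (Xbp1-Ire1 KO). IRE1 is the endoplasmic reticulum (ER) stress sensor whose RNase splices Xbp1 mRNA into the form that encodes the active transcription factor. The 19 libraries formed 6 groups of 3, except that cDC2 WT held 4. Total counts per library, in units of 1e6, were 12.8 to 13.7 in cDC1 WT, 11 to 12.2 in cDC1 Xbp1 KO and 11.3 to 16.2 in cDC1 Xbp1-Ire1 KO. They were 11.5 to 13.4 in cDC2 WT, 11.6 to 14.6 in cDC2 Xbp1 KO and 10.6 to 14.6 in cDC2 Xbp1-Ire1 KO. Marker transcripts followed the sort labels. Xcr1, a chemokine receptor of cDC1, lay at 813 to 1280 CPM (counts per 1e6 counts) in the cDC1 libraries and at 5.66 to 19.5 CPM in the cDC2 libraries. Sirpa, a receptor of cDC2, lay at 5.31 to 68.0 and at 1300 to 1700 CPM. These marker values are unscaled, and other CPM values of genes are scaled by TMM within a cell type unless stated. The labels do not say whether replicates were separate mice, so the p-values measure the spread between these samples, which may be technical.

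The WT libraries carried 2 description names in the labels: cDC1 WT replicates 1 and 2 and cDC2 WT replicates 1 and 2 were named after floxed alleles (fl-fl), and cDC1 WT replicate 3 and cDC2 WT replicates 3 and 4 were named WT. The names are not stated to be batches. In cDC1 a value against the WT-named library rests on 1 library, so a difference by name there is also one of that library. Immediate early genes, which are induced within minutes of handling or stimulation, had a mean log2 CPM of 8.09 to 8.14 in the fl-fl cDC1 libraries and 8.94 in the WT-named library, against 9.21 to 9.44 in Xbp1 KO and 8.13 to 8.52 in Xbp1-Ire1 KO. In cDC2 these means were 8.14 to 8.28 in the fl-fl libraries, 9.32 to 9.38 in the WT-named libraries, 9.29 to 9.89 in Xbp1 KO and 9.05 to 9.62 in Xbp1-Ire1 KO. List medians against the WT libraries of each name are therefore given for the lists that passed. Transcripts of pancreatic acinar cells, 15 that were not tested, summed to 1680 unscaled CPM in cDC1 Xbp1 KO replicate 3 and to at most 7.47 CPM in any other library, and counts without that replicate are given for its comparisons.

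The targeted genes were measured first. Xbp1 (ENSMUSG00000020484; GRCm38 chromosome 11, 5520659 to 5525893) lay at 233.4, 144.7 and 142.8 CPM in the cDC1 WT libraries, at 95.15, 89.72 and 112.8 CPM in cDC1 Xbp1 KO and at 352.6, 337 and 301.2 CPM in cDC1 Xbp1-Ire1 KO. In the cDC2 libraries it lay at 160.4, 102.8, 72.57 and 76.37 CPM in WT, at 44.39, 56.87 and 42.0 CPM in Xbp1 KO and at 63.31, 78.06 and 57.3 CPM in Xbp1-Ire1 KO. Ern1, the gene of IRE1 (ENSMUSG00000020715; chromosome 11, 106394650 to 106487852), lay at 22.42, 28.96 and 23.33 CPM in cDC1 WT, at 31.8, 33.12 and 26.74 CPM in cDC1 Xbp1 KO and at 71.33, 60.62 and 50.47 CPM in cDC1 Xbp1-Ire1 KO. Its cDC2 values were 26.19, 32.12, 26.49 and 20.61 CPM in WT, 30.65, 27.01 and 26.68 CPM in Xbp1 KO and 30.9, 21.17 and 21.84 CPM in Xbp1-Ire1 KO.

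By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, cDC1 Xbp1 counts fell in Xbp1 KO (log2 fold change −0.81 ± 0.18 SE, adjusted p = 0.0129, n = 3 and 3) and rose in Xbp1-Ire1 KO (0.93 ± 0.18, adjusted p = 0.00628). For Xbp1, cDC1 Xbp1 KO vs WT, the difference against the WT-named library alone was −0.51 (adjusted p = 0.138). The call was also lost without cDC1 WT replicate 1 (−0.53, adjusted p = 0.0573), cDC1 Xbp1 KO replicate 1 (−0.77, adjusted p = 0.0669) or cDC1 Xbp1 KO replicate 2 (−0.73, adjusted p = 0.0785). Ern1 counts rose in cDC1 Xbp1-Ire1 KO (1.29 ± 0.17, adjusted p = 0.000467) and did not pass the test in cDC1 Xbp1 KO (0.29 ± 0.17, adjusted p = 0.286). In cDC2 neither gene passed: Xbp1 differed by −1.11 ± 0.24 in Xbp1 KO (adjusted p = 0.247, n = 3 and 4) and by −0.64 ± 0.24 in Xbp1-Ire1 KO (adjusted p = 0.647). Counts over whole genes include transcripts that lack deleted exons, and the labels do not name the exons deleted, so these values neither check nor contradict the knockout labels.

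**Figure D1:**
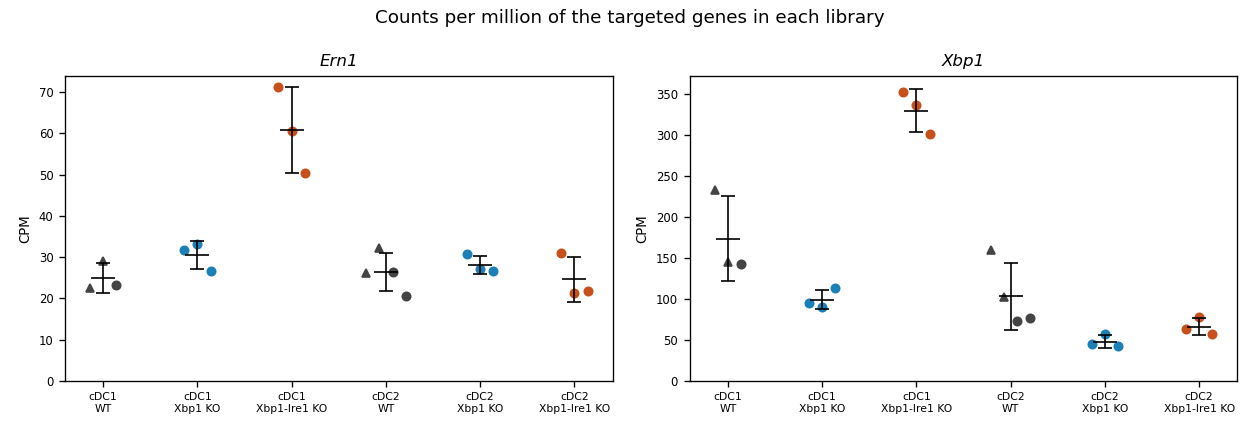
CPM (vertical axes) of Ern1 and Xbp1 in each library of the 6 groups (horizontal axes). Points are libraries, triangles are WT libraries named fl-fl, and bars are mean ± SD; the cDC1 Xbp1-Ire1 KO libraries lay above all other cDC1 libraries for both genes (50.47 to 71.33 CPM for Ern1, 301.2 to 352.6 CPM for Xbp1).

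The comparison of cDC1 from Xbp1 KO and WT asks what changes when Xbp1 is lost while IRE1 is present. Itgb2, the beta chain of the leukocyte integrins (chromosome 10, 77530252 to 77565708), fell from 416.1 ± 115 to 34.2 ± 2.56 CPM (SD, n = 3 each; log2 fold change −3.61, adjusted p = 3.16e-07). Tapbp, which encodes tapasin of the MHC class I peptide-loading complex (chromosome 17, 33915899 to 33929292), fell from 1370 ± 388 to 151.9 ± 30.3 CPM (−3.17, adjusted p = 1.1e-06). Asns, encoding asparagine synthetase (chromosome 6, 7675169 to 7693254), rose from 10.43 ± 2.83 to 84.82 ± 19 CPM (3.02, adjusted p = 4.31e-06).

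Genes were ranked here among those called with a mean log2 CPM of at least 3 and groups that did not overlap, so less abundant genes with larger changes are left out of this order. Beside Itgb2, the lowered genes with the largest changes were Fcrla, an Fc receptor-like protein retained in the ER (−4.58 ± 0.41 SE), the chemokine gene Ccl22 (−3.70 ± 0.37), Bloc1s1 of the complex that forms lysosome-related organelles (−3.58 ± 0.25), the RING finger gene Rnf130 (−3.34 ± 0.18) and Pbxip1 (−3.19 ± 0.23). Raised with the largest changes, after Asns, were the glycine transporter gene Slc6a9 (2.47 ± 0.33), the glutathione-degrading enzyme gene Chac1 (2.46 ± 0.29), Fam84b (2.37 ± 0.28), the mitochondrial nucleotide carrier gene Slc25a33 (2.19 ± 0.48) and the glycosyltransferase gene Gcnt2 (2.11 ± 0.53). For Slc25a33, cDC1 Xbp1 KO vs WT, and Gcnt2, cDC1 Xbp1 KO vs WT, the calls were lost against the WT-named library alone (1.10, adjusted p = 0.0819, and 0.96, adjusted p = 0.114). Without cDC1 WT replicate 1 their adjusted p-values were 0.0626 and 0.101, and without cDC1 Xbp1 KO replicate 2 they were 0.0552 and 0.0841. Gcnt2 also lost its call without cDC1 WT replicate 2 (adjusted p = 0.0578) and cDC1 Xbp1 KO replicate 1 (adjusted p = 0.0746). Gm2a, a lysosomal lipid-binding cofactor named after its values were seen, fell from 6619 ± 1210 to 1460 ± 106 CPM (−2.18 ± 0.14, adjusted p = 1.1e-06).

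Transcripts reported in earlier work as substrates of IRE1's RNase formed the list with the lowest median. Of 13 measured, 7 fell, among them Itgb2, Tapbp, Bloc1s1 and the lysosomal acetyltransferase gene Hgsnat (−2.81 ± 0.18), 0 rose and 6 did not pass, with 7 lower adjusted over the list alone. The list had a median log2 fold change of −1.77 and a camera adjusted p of 9.94e-09 (adjusted p = 0.0554 with an estimated correlation), and its medians were −1.71 against the fl-fl WT libraries and −1.73 against the WT-named one. Of 33 targets of ATF4 and CHOP, the transcription factors of the integrated stress response, 22 rose and 0 fell (25 and 0 adjusted over the list alone), including Cars (1.504 ± 0.135), the serine synthesis gene Phgdh (1.69 ± 0.18) and the folate enzyme gene Mthfd2 (1.05 ± 0.12). Their median was 0.97 (camera adjusted p = 1.13e-14; adjusted p = 0.0554 with an estimated correlation), 1.05 against fl-fl and 1.04 against the WT-named library. Cholesterol biosynthesis genes fell in 15 of 24 with 0 raised (0 and 20 adjusted over the list alone), including the sterol-sensing transcription factor gene Srebf2 (−1.97 ± 0.19), Sqle (−1.52 ± 0.16) and Cyp51 (−1.56 ± 0.17). Their median was −1.08 (camera adjusted p = 5.77e-13; adjusted p = 0.116 with an estimated correlation), −1.16 against fl-fl and −0.87 against the WT-named library.

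Genes of the secretory pathway fell as well. In N-glycosylation 11 of 30 fell and 0 rose (0 raised and 19 lowered adjusted over the list alone), among them the oligosaccharyltransferase genes Rpn1 (−2.27 ± 0.15) and Ddost (−1.24 ± 0.15) and the mannosyltransferase gene Alg1 (−2.62 ± 0.22). Camera gave this list an adjusted p of 1.17e-07 (adjusted p = 0.166 with an estimated correlation). In ER to Golgi transport 15 of 38 fell and 0 rose (0 and 20 adjusted over the list alone), including the cargo receptor gene Surf4 (−1.08 ± 0.14) and the coat gene Sec24d (−1.32 ± 0.19). Transport as a list had a camera adjusted p of 6.17e-06 (adjusted p = 0.116 with an estimated correlation). In the list of the ER translocon and signal peptidase 10 of 24 fell and 0 rose (1 raised and 13 lowered adjusted over the list alone), including Spcs3 (−1.15 ± 0.12) and Sec61a1 (−1.07 ± 0.14). For this list camera gave an adjusted p of 1.48e-05 (adjusted p = 0.232 with an estimated correlation). Of the ER chaperones and disulfide enzymes 12 of 27 fell, such as Erp44 (−2.55 ± 0.16) and P4hb (−1.37 ± 0.11), and 3 rose (3 and 12 adjusted over the list alone). Chaperones as a list had a camera adjusted p of 0.000494 (adjusted p = 0.0554 with an estimated correlation). Hspa5, the abundant ER chaperone BiP, was among those raised, from 1920 ± 684 to 5232 ± 244 CPM (1.45 ± 0.19, adjusted p = 0.00032). In ER-associated degradation 5 of 24 fell, such as the mannosidase-like gene Edem1 (−1.18 ± 0.14), and 1 rose (2 raised and 8 lowered adjusted over the list alone). Degradation had a camera adjusted p of 0.0244 (adjusted p = 0.192 with an estimated correlation) and lost its call against the WT-named library. Medians against the fl-fl and WT-named libraries were −0.59 and −0.34 for N-glycosylation, −0.43 and −0.28 for transport and −0.48 and −0.42 for the translocon. They were −0.38 and −0.22 for chaperones and −0.22 and −0.17 for degradation.

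MHC class I and lysosome genes were lower, and class II genes did not pass by camera. In MHC class I presentation 7 of 20 fell and 0 rose (0 and 9 adjusted over the list alone), including B2m, the class I light chain (−0.87 ± 0.15), with camera adjusted p = 0.000765 (adjusted p = 0.331 with an estimated correlation). Of the lysosomal genes 14 of 33 fell and 1 rose (2 raised and 17 lowered adjusted over the list alone), including Lamp1 (−2.58 ± 0.23) and Tpp1 (−1.999 ± 0.211). The lysosome list had a camera adjusted p of 0.000151 (adjusted p = 0.233 with an estimated correlation). Its median of −0.38 was −0.43 against the fl-fl libraries (19 lower) and −0.10 against the WT-named one (5 lower). In the integrin and adhesion list 6 of 24 fell and 1 rose (1 and 9 adjusted over the list alone), including the tetraspanin gene Cd81 (−2.67 ± 0.21), with camera adjusted p = 0.0152 (adjusted p = 0.232 with an estimated correlation). Genes raised during homeostatic maturation of dendritic cells fell in 15 of 48, such as Ccl22 and Relb (−0.86 ± 0.15), and 1 rose (2 and 20 adjusted over the list alone). Maturation had a camera adjusted p of 7.44e-05 (adjusted p = 0.609 with an estimated correlation). Class I medians were −0.345 against fl-fl and −0.175 against the WT-named library, integrin medians −0.26 and −0.21 and maturation medians −0.42 and −0.93. Integrins lost their call against the WT-named library and maturation against the fl-fl ones. Proliferation genes fell in 7 of 32, such as Ccnb2 (−1.22 ± 0.17), and 0 rose (0 and 17 adjusted over the list alone), with camera adjusted p = 0.000109 (adjusted p = 0.569 with an estimated correlation). Their median of −0.69 was −0.77 against the fl-fl libraries and −0.22 against the WT-named one.

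Immediate early genes rose in 6 of 23, including Fosb (1.99 ± 0.26) and Egr2 (1.17 ± 0.20), and 0 fell (14 raised and 1 lowered adjusted over the list alone). Early genes had a camera adjusted p of 1.01e-05 (adjusted p = 0.233 with an estimated correlation). Against the WT-named library 1 of the 23 rose (median 0.46), and against the fl-fl libraries 15 rose and 1 fell (median 0.66). The T cell list, of 6 measured transcripts near the detection limit, was lower (camera adjusted p = 0.0225; adjusted p = 0.166 with an estimated correlation). Its medians were −0.99 against fl-fl, where it lost its call, and −0.93 against the WT-named library. In the cDC1 identity list, which did not pass (camera adjusted p = 0.0631), 4 of 28 rose and 3 fell (6 and 3 adjusted over the list alone). Among them Notch4 (−2.43 ± 0.19) and Naaa (−1.67 ± 0.14) fell, and the nucleic acid and profilin sensors Tlr3 (0.71 ± 0.12) and Tlr11 (0.71 ± 0.12) rose. Tlr11 lies in a stretch of chromosome 14 described under other observations, so for it a difference between the mouse lines is not excluded. The lists that did not pass in this comparison had camera adjusted p-values of 0.0581 for MHC class II presentation, 0.162 for red pulp macrophages, 0.172 for glycolysis, 0.294 for LXR targets with fatty acid synthesis, 0.294 for B cells and 0.294 for erythroid cells. They were 0.445 for plasma cells, 0.514 for interferon-stimulated genes, 0.681 for neutrophils, 0.712 for plasmacytoid dendritic cells, 0.813 for cDC2 identity, 0.821 for apoptosis and p53 targets and 0.821 for monocytes. Median, mean and test differed in sign for cDC2 identity, apoptosis, B cells, monocytes and plasmacytoid dendritic cells. The NK cell list and the list of Y-linked genes with Xist had 4 measured members each in cDC1 and were not tested there, and 0 mitochondrially encoded genes were measured.

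In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1270 of 11353 genes between cDC1 of Xbp1 KO and WT, 486 higher and 784 lower. Camera called 15 of 29 lists, 2 up and 13 down, of which 0 passed with an estimated correlation. Splits of the libraries that mixed the groups called lists too, as given below for each comparison. Over the 29 lists fry called 14, which included MHC class II (fry adjusted p = 0.00618). Maturation (0.15) and proliferation (0.139) did not pass by fry. The count was 2926 against the fl-fl WT libraries, with 1246 genes shared, and 345 against the WT-named library, with 284 shared. Leaving out cDC1 WT replicate 1 or 2 gave 471 or 620, leaving out WT replicate 3 gave 2926, and leaving out Xbp1 KO replicate 1 or 2 gave 550 or 498. Without Xbp1 KO replicate 3, which held the pancreatic transcripts, it was 897. A fit of these groups alone called 828. Groups did not overlap for 3419 genes, 30.1% of those tested, where chance gives 10% for 3 against 3.

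The comparison of cDC1 from Xbp1-Ire1 KO and WT asks what remains when IRE1 is lost together with Xbp1. Trib3, a pseudokinase induced by CHOP (chromosome 2, 152337422 to 152344032), rose from 3.14 ± 0.655 to 105.4 ± 21.7 CPM (SD, n = 3 each; log2 fold change 5.06, adjusted p = 1.98e-06), and Asns rose to 184.1 ± 51.2 CPM (4.14, adjusted p = 7.12e-07). Hspa5 (chromosome 2, 34771970 to 34777547) rose to 6955 ± 570 CPM (1.86, adjusted p = 6.47e-05). Apol7c, an apolipoprotein L family gene of the maturation list (chromosome 15, 77524852 to 77533316), fell from 940.4 ± 126 to 178.1 ± 53.1 CPM (−2.40, adjusted p = 4.84e-05). Itgb2, lowered in Xbp1 KO, was raised here to 884.2 ± 54.4 CPM (1.09, adjusted p = 0.00131).

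**Figure D2:**
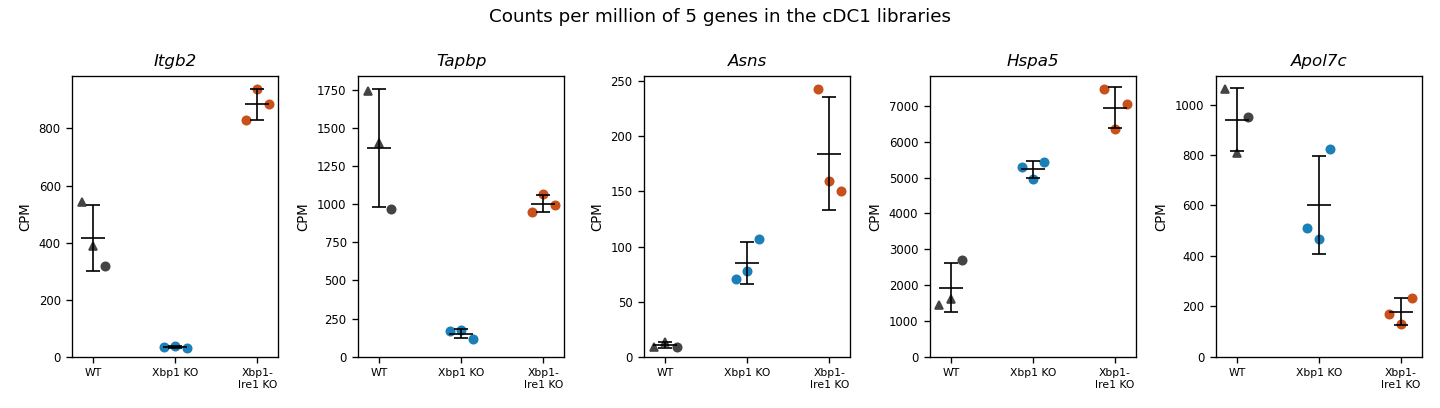
CPM (vertical axes) of Itgb2, Tapbp, Asns, Hspa5 and Apol7c in the 9 cDC1 libraries by genotype (horizontal axes). Points are libraries, triangles are WT libraries named fl-fl, and bars are mean ± SD; Itgb2 and Tapbp were lowest in Xbp1 KO (34.2 ± 2.56 and 151.9 ± 30.3 CPM), and Asns was lowest in WT (10.43 ± 2.83 CPM).

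Under the same limits of abundance and overlap, other genes raised by the most were Ddit3, which encodes CHOP (3.99 ± 0.34 SE), the transporter genes Slc6a9 (3.97 ± 0.34) and Slc1a4 (3.83 ± 0.36) and Phgdh (3.27 ± 0.19). Lowered by the most were Tmem176a (−3.63 ± 0.32), the protease gene Asprv1 (−3.63 ± 0.38), Fscn1, encoding the actin-bundling protein fascin (−3.19 ± 0.38), Tnfrsf4, encoding OX40 (−2.94 ± 0.49), the adenosine receptor gene Adora2a (−2.94 ± 0.43) and the Notch ligand gene Jag1 (−2.86 ± 0.42). Cox6a2, a cytochrome oxidase subunit, rose from 0.421 ± 0.18 to 82.97 ± 25.3 CPM (7.59 ± 0.40). It lies on chromosome 7 within the span of Itgad, on the opposite strand, and both are described for cDC2. In the groups of all these genes the 3 libraries did not overlap.

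Of the 33 ATF4 and CHOP targets 27 rose and 0 fell (29 and 0 adjusted over the list alone), including Cebpb (2.77 ± 0.15). Their median was 1.73 (1.74 against fl-fl and 1.77 against the WT-named library), with camera adjusted p = 3.9e-33, and this list alone passed with an estimated correlation (adjusted p = 0.0152). Maturation genes fell in 32 of 48 and rose in 0 (0 and 36 adjusted over the list alone), including Relb (−1.53 ± 0.15), Marcksl1 (−1.999 ± 0.227) and Eno3 (−1.94 ± 0.23). Their median was −1.22, −0.95 against fl-fl and −1.46 against the WT-named library, with camera adjusted p = 5.26e-21 (adjusted p = 0.312 with an estimated correlation). The share of already mature cells in each sort was not measured. Ccr7, the homing receptor of mature dendritic cells, named after its values were seen, fell from 849.8 ± 477 to 123.2 ± 55.6 CPM (−2.79 ± 0.41, adjusted p = 0.000939). ER chaperones rose in 12 of 27 and fell in 3 (12 and 5 adjusted over the list alone). Raised were Hsp90b1 (1.71 ± 0.15), Pdia4 (1.27 ± 0.13) and Pdia3 (1.03 ± 0.11), and the list had a camera adjusted p of 0.00259 (adjusted p = 0.11 with an estimated correlation). Chaperone medians were 0.38 against fl-fl and 0.32 against the WT-named library.

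The reported IRE1 substrates, lowered in Xbp1 KO, did not pass here: 1 of 13 rose, which was Itgb2, 0 fell, the median was 0.03 and camera's adjusted p was 0.509. ER to Golgi transport genes fell in 8 of 38, such as Sec24c (−0.81 ± 0.12) and Copa (−0.60 ± 0.12), and rose in 0 (0 and 17 adjusted over the list alone; camera adjusted p = 4.16e-06; adjusted p = 0.167 with an estimated correlation). Translocon genes fell in 5 of 24 and rose in 0, such as Ssr1 (−0.74 ± 0.12), with the same counts adjusted over the list alone (camera adjusted p = 0.00788; adjusted p = 0.503 with an estimated correlation). In N-glycosylation 6 of 30 fell and 1 rose (1 and 7 adjusted over the list alone; camera adjusted p = 0.0485; adjusted p = 0.559 with an estimated correlation), and the median of −0.15 was −0.27 against fl-fl and 0.05 against the WT-named library. Cholesterol genes fell in 3 of 24 and rose in 0 (0 and 4 adjusted over the list alone; camera adjusted p = 0.0147; adjusted p = 0.559 with an estimated correlation). LXR targets and fatty acid genes fell in 2 of 20, such as the cholesterol exporter gene Abcg1 (−1.66 ± 0.22), and rose in 1 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0147; adjusted p = 0.439 with an estimated correlation). MHC class II genes fell in 5 of 16 and rose in 0 (0 and 7 adjusted over the list alone; camera adjusted p = 0.0132; adjusted p = 0.355 with an estimated correlation). Lysosomal genes fell in 5 of 33, such as Cd63 (−2.79 ± 0.40), and rose in 0 (0 and 7 adjusted over the list alone; camera adjusted p = 0.00347; adjusted p = 0.439 with an estimated correlation). The cholesterol, LXR, class II and lysosome lists lost their calls against the WT-named library. Against it 2 cholesterol genes rose and 0 fell (median −0.11) and 1 lysosomal gene rose and 2 fell (−0.04), while against fl-fl 0 and 4 (−0.28) and 1 and 16 (−0.35) did. Medians against the fl-fl and WT-named libraries were −0.39 and −0.19 for LXR targets, −0.41 and −0.215 for class II, −0.38 and −0.20 for transport and −0.21 and −0.205 for the translocon.

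Transcripts of other cells moved with the Xbp1-Ire1 KO libraries at low levels. The neutrophil list was higher (1 of 10 raised, 4 adjusted over the list alone; median 2.69; camera adjusted p = 0.00228; adjusted p = 0.312 with an estimated correlation), with Ngp at 11.4 ± 9.28 CPM. The erythroid list was higher (1 of 5 raised, 4 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.439 with an estimated correlation), with Car2 at 20.6 ± 13.2 CPM. Transcripts of T cells were lower (1 of 6 lowered, 2 adjusted over the list alone; camera adjusted p = 0.0132; adjusted p = 0.196 with an estimated correlation). Medians against the fl-fl and WT-named libraries were 2.73 and 3.11 for neutrophils, 3.21 and 1.87 for erythroid cells and −0.52 and −0.34 for T cells. The erythroid call was lost against the WT-named library and the T cell call against either name. Lists that did not pass had camera adjusted p-values of 0.0722 for immediate early genes, 0.141 for cDC2 identity, 0.141 for plasma cells, 0.147 for interferon-stimulated genes, 0.156 for plasmacytoid dendritic cells, 0.25 for integrins and 0.25 for MHC class I. They were 0.449 for monocytes, 0.506 for ER-associated degradation, 0.633 for red pulp macrophages, 0.643 for glycolysis, 0.65 for B cells, 0.659 for cDC1 identity, 0.709 for proliferation and 0.709 for apoptosis and p53 targets. Median, mean and test differed in sign for apoptosis, B cells and plasma cells.

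The same test called 880 of 11353 genes, 345 higher and 535 lower. Camera called 13 of 29 lists, 4 up and 9 down, of which 1 passed with an estimated correlation and 7 by fry. Against the fl-fl libraries the gene count was 1966 with 844 shared, and against the WT-named library it was 580 with 375 shared, where 7 lists were called. Without cDC1 WT replicate 1 it was 460, without WT replicate 3 it was 1966, and without Xbp1-Ire1 KO replicate 1 or 3 it was 430 or 462. DESeq2 called 1356 genes, and a fit of these groups alone 575.

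The direct comparison of cDC1 from Xbp1-Ire1 KO and Xbp1 KO asks what the further loss of IRE1 changes. Itgb2 differed by 4.69 ± 0.19 SE (adjusted p = 1.16e-08, n = 3 and 3), and Rnf130 (4.44 ± 0.18), Fcrla (4.38 ± 0.41), Bloc1s1 (4.12 ± 0.25), Pbxip1 (4.08 ± 0.24) and Fam134c (3.94 ± 0.43) were the other genes raised by the most under the limits given for Xbp1 KO. Lowered by the most under them were the sulfotransferase gene Sult1a1 (−2.53 ± 0.29), Tmcc3 (−2.24 ± 0.45), the class II gene H2-Eb2 (−2.05 ± 0.35), Ccr7 (−2.01 ± 0.40), the claudin gene Cldn1 (−1.88 ± 0.26) and Synpo (−1.84 ± 0.27). Gm2a, chosen after its values were seen, rose from 1460 ± 106 to 3944 ± 236 CPM (1.43 ± 0.14), Ern1 rose by 0.99 ± 0.17 (adjusted p = 0.00235) and Xbp1 rose by 1.73 ± 0.18 (adjusted p = 3.66e-05).

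ER chaperones rose in 19 of 27 and fell in 1 (19 and 2 adjusted over the list alone), including Dnajb11 (2.18 ± 0.12) and Erp44 (2.72 ± 0.16), with camera adjusted p = 1.37e-10, the 1 list that passed with an estimated correlation (adjusted p = 0.00753). Reported IRE1 substrates rose in 7 of 13 and fell in 0 (8 and 0 adjusted over the list alone), including Hgsnat (3.27 ± 0.18) and the ganglioside synthase gene St3gal5 (1.90 ± 0.13), with a median of 1.89 and camera adjusted p = 4.31e-08 (adjusted p = 0.051 with an estimated correlation). ATF4 and CHOP targets rose in 20 of 33 and fell in 0 (25 and 0 adjusted over the list alone), such as Trib3 (3.33 ± 0.31) and Sesn2 (1.24 ± 0.14; camera adjusted p = 2.36e-11; adjusted p = 0.0755 with an estimated correlation). Cholesterol genes rose in 12 of 24 and fell in 0 (14 and 0 adjusted over the list alone), such as Srebf2 (1.97 ± 0.19) and Fdps (1.71 ± 0.18; camera adjusted p = 7.47e-09; adjusted p = 0.218 with an estimated correlation). N-glycosylation genes rose in 8 of 30, such as Rpn1 (2.31 ± 0.15), and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000824; adjusted p = 0.439 with an estimated correlation). Translocon genes rose in 3 of 24, such as Spcs3 (0.89 ± 0.12), and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 0.0391; adjusted p = 0.551 with an estimated correlation). MHC class I genes rose in 6 of 20, such as Tapbp (2.72 ± 0.21), and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0327; adjusted p = 0.551 with an estimated correlation). Proliferation genes rose in 8 of 32, such as Tyms (1.18 ± 0.21), and fell in 0 (16 and 0 adjusted over the list alone; camera adjusted p = 1.84e-05; adjusted p = 0.551 with an estimated correlation).

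Maturation genes fell in 18 of 48, such as Apol7c (−1.76 ± 0.24), and rose in 2 (2 and 29 adjusted over the list alone; camera adjusted p = 6.49e-09; adjusted p = 0.491 with an estimated correlation). Immediate early genes fell in 15 of 23, such as Egr1 (−1.40 ± 0.24), and rose in 0 (0 and 19 adjusted over the list alone; camera adjusted p = 1.03e-09; adjusted p = 0.218 with an estimated correlation). The cDC1 identity list was lower (8 of 28 lowered, 2 raised; 9 and 2 adjusted over the list alone; camera adjusted p = 0.0389; adjusted p = 0.401 with an estimated correlation), although Notch4 (2.61 ± 0.19) and Naaa (1.64 ± 0.14) rose. The neutrophil list was higher (2 of 10 raised; 6 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.324 with an estimated correlation). So was the erythroid list (3 of 5 raised; 5 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.403 with an estimated correlation), with Car2 at 20.6 against 2.46 CPM. The other 16 lists did not pass, and plasma cells were the list whose median and test differed in sign.

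The test called 1437 of 11353 genes, 810 higher and 627 lower, and camera called 13 of 29 lists, 10 up and 3 down. With an estimated correlation 1 list passed, and over the 29 lists fry called 12. The gene count was 709 without Xbp1-Ire1 KO replicate 1, 778 without replicate 3 of that group, 658 without Xbp1 KO replicate 1 and 648 without Xbp1 KO replicate 2. It was 1297 without the library with pancreatic transcripts and 2239 in a fit of these groups alone.

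Within cDC1, 284 genes changed the same way in both knockouts against WT, 116 up and 168 down, and 24 changed in opposite ways. Independent lists of these sizes would share 51.7 genes. Simulations without any effect but with shared WT libraries gave a median of 0 and at most 2. Where no gene changes few genes can be called, so these overlaps cannot show how many genes lists of the real sizes share through common libraries. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.503, against a median of 0.498 in the simulations from the shared WT libraries, and their covariance exceeded the simulated one by 0.166. Further, 534 genes changed in Xbp1 KO against WT and changed back in Xbp1-Ire1 KO against Xbp1 KO, of which 394 were lowered and then higher again, such as Itgb2, Tapbp and Srebf2, and 140 the reverse. Independence would give 82.8, and the simulations gave 0 with the same limit. The correlation was −0.502 against −0.504 simulated and the covariance difference was −0.165. The 3 WT libraries were divided between the comparisons in 6 ways, 2 to one and 1 to the other, chosen after seeing the data. There r was 0.109 to 0.245. It was lowest where Xbp1 KO was set against the fl-fl libraries and Xbp1-Ire1 KO against WT replicate 3. Each division leaves a group of 1 library, so counts of shared genes are not given. In 6 such divisions of the Xbp1 KO libraries r was −0.184 to −0.0609. Without cDC1 WT replicate 1, 2 or 3 the 284 became 95, 165 or 1119, without Xbp1 KO replicate 1, 2 or 3 they became 139, 127 or 178, and without Xbp1-Ire1 KO replicate 1 or 3 they became 161 or 156. For the 534 the values were 291, 325 and 1172 without WT replicate 1, 2 and 3, 261 and 244 without Xbp1 KO replicate 1 and 2, and 344 and 328 without Xbp1-Ire1 KO replicate 1 and 3.

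**Figure D3:**
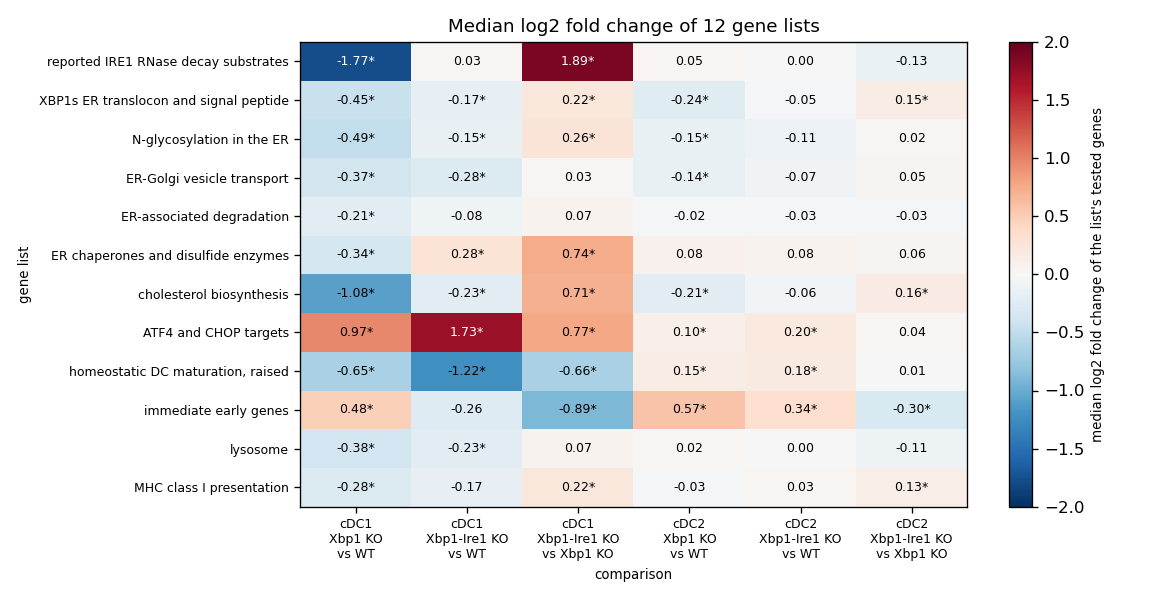
Median log2 fold change (colour and printed value) of the measured genes of 12 lists (vertical axis) in the 6 comparisons of genotypes (horizontal axis). Stars mark a camera adjusted p under 0.05 at the preset correlation; the reported IRE1 substrates had medians of −1.77, 0.03 and 1.89 in the cDC1 comparisons and −0.13 to 0.05 in the cDC2 comparisons.

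In cDC2, far fewer genes passed. Between cDC2 of Xbp1 KO and WT, which asks the same question in the other subset, Plcb4, a phospholipase C gene (chromosome 2, 135659011 to 136014593), rose from 1.83 ± 1.62 to 45.23 ± 5.55 CPM (log2 fold change 4.64, adjusted p = 0.000403, n = 4 and 3). Its neighbour Plcb1 (chromosome 2, 134786067 to 135475258) was counted 1 time over the 4 WT libraries and 329 times over the 3 Xbp1 KO libraries, a ratio of 405 (95% counting interval 72.2 to 16100). Cox6a2 (chromosome 7, 128205435 to 128206387) rose by 4.90 ± 0.41 SE and the integrin gene Itgad (chromosome 7, 128154376 to 128223816) by 2.76 ± 0.37. The other raised genes were the myotubularin gene Mtmr9 (2.42 ± 0.40; chromosome 14, 63519651 to 63543982), the histone chaperone gene Supt16 (1.82 ± 0.25; chromosome 14, 52160414 to 52197416), Arl5c (1.74 ± 0.25; chromosome 11, 97989578 to 97996181) and Arf2 (1.499 ± 0.195; chromosome 11, 103966739 to 103985337). Lowered were Lsm12 (−1.15 ± 0.15; chromosome 11, 102162497 to 102185296), the Mediator subunit gene Med1 (−0.79 ± 0.13; chromosome 11, 98152154 to 98193293), Mettl17 (−2.70 ± 0.43; chromosome 14, 51884842 to 51893039) and Adamdec1 (chromosome 14, 68563380 to 68582095). Adamdec1 had 387 counts over the WT libraries and 0 over the Xbp1 KO libraries, at least 105-fold lower against a floor of 3 counts over the group. Plcb1, Mettl17 and Adamdec1 fall outside the rule for named genes and were chosen after their values were seen. Intervals and floors cover counting error only. All of these genes lie on chromosomes 2, 7, 11 and 14, several of them close together. Differences between the mouse lines other than Xbp1 are therefore not excluded, and positions are weighed below for the genes shared with cDC1. For Arl5c, Mtmr9 and Adamdec1, which are not among those, this was not tested.

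These 12 genes, 8 higher and 4 lower, were all that edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called of 11646 in cDC2 Xbp1 KO, while 1127 had an unadjusted p under 0.05. The count was 740 against the fl-fl WT libraries and 6 against the WT-named ones, DESeq2 called 47, and without the low-count filter 21 were called. Mtmr9, cDC2 Xbp1 KO vs WT, lost its call without any 1 of the WT libraries (adjusted p = 0.167, 0.148, 0.0845 and 0.12 without replicates 1 to 4) and without Xbp1 KO replicate 1 or 2 (0.053 and 0.22). Med1, cDC2 Xbp1 KO vs WT, lost its call without WT replicates 1 to 3 (adjusted p = 0.0711, 0.0853 and 0.07), without any 1 of the Xbp1 KO libraries (0.254, 0.175 and 0.218 without replicates 1 to 3) and in a fit of the 2 groups alone (0.0745). Mettl17, cDC2 Xbp1 KO vs WT, lost it without WT replicates 1 to 3 (0.0876, 0.0939 and 0.0503), without Xbp1 KO replicates 1 to 3 (0.199, 0.109 and 0.132) and with limma-voom (0.188). Against the WT-named libraries the calls of Mtmr9, Med1, Mettl17, Supt16, Itgad and Arl5c were lost. Counting all alternatives, Med1 and Mettl17 lost their calls in 9 each, Mtmr9 in 7, Arl5c in 2, and Supt16 and Itgad in 1 each.

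In cDC2 of Xbp1 KO camera called 12 of 30 lists, 6 up and 6 down, and 0 with an estimated correlation or by fry. Immediate early genes were higher, with a median of 0.57 (camera adjusted p = 1.07e-06; adjusted p = 0.573 with an estimated correlation), which was 0.90 against the fl-fl and 0.23 against the WT-named libraries. Homeostatic maturation (median 0.15, camera adjusted p = 0.000144), ATF4 and CHOP targets (0.10, adjusted p = 0.00655) and cDC2 identity (0.14, adjusted p = 0.0131) were higher, each with adjusted p = 0.573 with an estimated correlation. No member of these lists was itself among the genes called in this comparison. Integrins (0.14, camera adjusted p = 0.0387) and red pulp macrophages (1.09, camera adjusted p = 0.00316) were higher, each with adjusted p = 0.597 with an estimated correlation. Interferon-stimulated genes (−0.32, camera adjusted p = 9.9e-05), the translocon (−0.24, adjusted p = 0.00275), cholesterol biosynthesis (−0.22, adjusted p = 0.00582), ER to Golgi transport (−0.14, adjusted p = 0.0358) and N-glycosylation (−0.15, adjusted p = 0.0462) were lower, each with adjusted p = 0.573 with an estimated correlation. Proliferation was lower too (−0.36, camera adjusted p = 0.000156; adjusted p = 0.597 with an estimated correlation). Medians against the fl-fl and WT-named libraries were 0.28 and 0.09 for maturation, 0.16 and 0.08 for ATF4 and CHOP targets, 0.10 and 0.21 for cDC2 identity, −0.02 and 0.25 for integrins and 1.16 and 1.07 for macrophages. They were −0.40 and −0.32 for interferon-stimulated genes, −0.33 and −0.17 for the translocon, −0.32 and −0.085 for cholesterol, −0.16 and −0.08 for transport, −0.19 and −0.02 for N-glycosylation and −0.39 and −0.30 for proliferation. Calls lost against the WT-named libraries were those of maturation, ATF4 and CHOP targets, cholesterol, transport and N-glycosylation. Those of integrins, macrophages, cDC2 identity, transport and proliferation were lost against the fl-fl ones. The reported IRE1 substrates had a median of 0.05 and did not pass (adjusted p = 0.795). NK cells, measurable in cDC2, did not pass (adjusted p = 0.795). Median, mean and test differed in sign for ER-associated degradation, cDC1 identity, apoptosis and T cells. The list count was 7 against the fl-fl libraries, and 7 without Xbp1 KO replicate 2.

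Between cDC2 of Xbp1-Ire1 KO and WT, 3 genes passed, all higher: Plcb4 (4.51 ± 0.47 SE), Cox6a2 (5.27 ± 0.41) and, chosen after its values were seen, Plcb1 with 251 counts against 1 (ratio 341, 95% counting interval 60.7 to 13500). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were lower, 877 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 3. The count was 485 against the fl-fl libraries and 3 against the WT-named ones. Of 30 lists 5 passed and 0 held with an estimated correlation or by fry. These were proliferation (median 0.45, camera adjusted p = 1.41e-06), homeostatic maturation (0.18, adjusted p = 0.000108), ATF4 and CHOP targets (0.20, adjusted p = 0.0023), erythroid cells (1.48, adjusted p = 0.0114) and immediate early genes (0.34, adjusted p = 0.0165), each with adjusted p = 0.973 with an estimated correlation. Immediate early genes had a median of 0.70 against the fl-fl and −0.06 against the WT-named libraries, maturation 0.35 and 0.07, ATF4 and CHOP targets 0.25 and 0.05, proliferation 0.37 and 0.40 and erythroid cells 1.97 and 1.62. Against the WT-named libraries the first 3 of these calls were lost, and against fl-fl the erythroid call. Signs differed between median, mean and test for ER-associated degradation, reported IRE1 substrates, cDC1 identity, B cells, T cells and plasmacytoid dendritic cells. The list count was 3 without Xbp1-Ire1 KO replicate 1 and 3 without replicate 2.

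Between cDC2 of Xbp1-Ire1 KO and Xbp1 KO, 4 of 11646 genes passed. Lsm12 (1.34 ± 0.15 SE), Itgb2 (0.69 ± 0.10, from 730.6 ± 33.6 to 1181 ± 11 CPM) and Adamdec1, which was at least 78.4-fold higher (213 counts against 0) and was chosen after its values were seen, were higher, and Arf2 was lower (−1.53 ± 0.21). The unadjusted count was 960 and DESeq2 called 11. The 4 became 2, 8 and 2 without Xbp1-Ire1 KO replicate 1, 2 and 3 and 2 without Xbp1 KO replicate 1. The call of Itgb2, cDC2 Xbp1-Ire1 KO vs Xbp1 KO, was lost without any 1 of the 6 libraries (adjusted p 0.0689 to 0.333). For Arf2, cDC2 Xbp1-Ire1 KO vs Xbp1 KO, it was lost without Xbp1-Ire1 KO replicate 1 or 3 (0.222 and 0.157) or Xbp1 KO replicate 1 or 2 (0.0813 and 0.0805). Camera called 9 of 30 lists, 6 up and 3 down, and 0 with an estimated correlation or by fry. Proliferation (median 0.68, camera adjusted p = 3.93e-17, with 20 of 32 higher adjusted over the list alone), interferon-stimulated genes (0.40, adjusted p = 6.25e-08), erythroid cells (1.84, adjusted p = 0.000868), the translocon (0.15, adjusted p = 0.0162) and MHC class I (0.13, adjusted p = 0.0455) were higher, each with adjusted p = 0.714 with an estimated correlation. Cholesterol biosynthesis was higher (0.16, camera adjusted p = 0.0455; adjusted p = 0.849 with an estimated correlation). The cDC2 identity (−0.17, camera adjusted p = 0.0397) and B cell lists (−0.50, adjusted p = 0.0498) were lower, each with adjusted p = 0.714 with an estimated correlation, and so were immediate early genes (−0.30, camera adjusted p = 0.0397; adjusted p = 0.86 with an estimated correlation). Signs differed for ATF4 and CHOP targets, maturation, glycolysis, apoptosis, T cells, NK cells and monocytes. The list count was 4 and 5 without Xbp1-Ire1 KO replicate 1 and 3 and 5 without Xbp1 KO replicate 1. In cDC2, 3 genes changed the same way in both knockouts (0.00206 under independence; covariance difference 0.056) and 3 changed back, which were Lsm12, Arf2 and Adamdec1 (0.00172 under independence; covariance difference −0.0462). In 6 divisions of the 4 WT libraries between the comparisons, 2 to 3 genes were shared and r was 0.0964 to 0.214. The 3 that changed back became 6 without Xbp1-Ire1 KO replicate 2.

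Whether the subsets responded differently was tested as an interaction over all 19 libraries. The fit treated them as independent, although some cDC1 and cDC2 libraries may come from the same mice. Genes are given here by smallest adjusted p and not by size of the difference. For Xbp1 KO against WT, those lowered more in cDC1 included Rnf130 (difference of log2 fold changes −3.12 ± 0.19 SE) and Itgb2 (−3.20 ± 0.19, adjusted p = 2.92e-09 by edgeR's quasi-likelihood test). They also held Hgsnat (−2.64 ± 0.20), Erp44 (−2.51 ± 0.19), Pbxip1 (−3.17 ± 0.25), Leprot (−2.25 ± 0.18), Bloc1s1 (−3.42 ± 0.29), BC004004 (−2.09 ± 0.18), Rpn1 (−2.22 ± 0.20) and Tapbp (−2.89 ± 0.26). For Xbp1-Ire1 KO against WT the prostaglandin receptor gene Ptger3 (5.65 ± 0.40, with 2, 3 and 7 counts in the cDC1 WT and 267, 253 and 209 in the cDC1 Xbp1-Ire1 KO libraries) was more positive in cDC1. So were Phgdh (3.18 ± 0.26), Sars (1.76 ± 0.18), Mthfd2 (1.71 ± 0.17), Eif4ebp1 (2.16 ± 0.23) and Hspa9 (1.40 ± 0.16). More negative there were Tmem176a (−3.31 ± 0.34), Apol7c (−2.69 ± 0.32), Tmem176b (−2.53 ± 0.31) and Ccng2 (−1.93 ± 0.24). Between the knockouts, Rnf130 (4.11 ± 0.20), Itgb2 (3.98 ± 0.20), Ptger3 (6.64 ± 0.44), the glutamine transporter gene Slc1a5 (3.24 ± 0.25) and Dnajb11 (2.00 ± 0.15) were among those more positive in cDC1.

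By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the effect differed between subsets for 264 of 12185 genes in Xbp1 KO against WT (40 more positive and 224 more negative in cDC1), for 272 in Xbp1-Ire1 KO against WT (92 and 180) and for 261 between the knockouts (222 and 39). With the WT-named libraries alone, chosen after seeing the data, the first count was 173. Without cDC1 WT replicate 3 it was 418, and without cDC1 Xbp1-Ire1 KO replicate 1 the second was 170. Reported IRE1 substrates were lowered more in cDC1 by Xbp1 loss (median difference −1.89, camera adjusted p = 1.4e-17, and 3.15e-05 with an estimated correlation), and ATF4 and CHOP targets were raised more (0.73, adjusted p = 4.04e-12, and 0.00812 with an estimated correlation). Cholesterol biosynthesis (−0.83), chaperones (−0.29), N-glycosylation (−0.34), ER to Golgi transport (−0.30) and lysosome genes (−0.41) differed too, each with adjusted p = 0.0318 with an estimated correlation. In Xbp1-Ire1 KO, ATF4 and CHOP targets (1.64, adjusted p = 4.88e-05 with an estimated correlation) were raised more and maturation genes (−1.37, adjusted p = 0.0386 with an estimated correlation) were lowered more in cDC1. In both subsets 9 genes changed the same way in Xbp1 KO (0.631 under independence; 5 without cDC1 WT replicate 1, 5 without cDC1 WT replicate 2 and 5 without cDC1 Xbp1 KO replicate 2), and 3 did in Xbp1-Ire1 KO (0.0905 under independence). The 9 were Lsm12, Arf2, Supt16, Plcb1, Plcb4, Itgad, Cox6a2 and, with the losses of cDC2 calls given above, Med1 and Mettl17. In cDC1, Plcb1 had 0 counts in the WT libraries and was at least 19.8-fold higher in Xbp1 KO and at least 11-fold higher in Xbp1-Ire1 KO.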

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

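Tests chosen only after the results were seen were those against the WT libraries of each name, the tests of the share of mature cells and of the immediate early level, the 4 tests on genes changed in both cell types, and the control hairpins and the strata of length and GC.

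Total counts in cDC2 WT held a library far from the others: replicate 2, with 13.4 in units of 1e6 counts, gave a Dixon ratio of 0.833, above the 95% critical value, in 1 of 28 quantities tested, where chance gives about 1 in 20. A difference between cell types was found by an interaction test for 264 genes in Xbp1 KO against WT, for 272 in Xbp1-Ire1 KO against WT and for 261 between the knockouts. A signal outside the tested genes came from pancreatic acinar transcripts, whose marker list was written after they were noticed. The 15 of its 17 genes that were not tested summed to 1680 CPM (20555 counts, unscaled) in cDC1 Xbp1 KO replicate 3, with Cela2a at 563 and Cpb1 at 193 CPM, and to 7.47 CPM in the next library. Cela1, which was tested, lay at 561 CPM in that replicate beside this sum.

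Maturation genes fell in cDC1 of Xbp1-Ire1 KO, with a list median of −1.22. A difference between the WT libraries of the 2 names as the whole cause is argued against by the higher of the medians within a name, −0.952. A lower immediate early level of the libraries is not decided. The mean level lay 0.268 ± 0.132 SE log2 CPM above that of the fl-fl WT libraries, against which the maturation list fell. The immediate early genes were split there, with a median log2 fold change of −0.112, 8 higher and 7 lower. Against the WT-named library their median was −0.589. A covariate for the level, planned first, was dropped since the level hardly differed from all WT libraries (−0.007). A smaller share of mature cells in the sort cannot be told apart from lower expression per cell, since the share was not measured. The interquartile range of the members' log2 fold changes was 1.46, with quartiles of −2.06 and −0.596, and a share that differs could give such a range where members differ in how far mature cells exceed the rest. A direct effect of genotype stays open beside this share and the immediate early level.

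Of the 9 genes changed in both cell types of Xbp1 KO, Cox6a2 lies within the span of Itgad. Each of the 9 lay within 10 Mb of another of them. With random draws the number reached at most 7, which gives a permutation p of 1e-04, the smallest that 10000 draws can give, and strain segments or transgene copies that differ between the mouse lines are a candidate explanation. A segment carried with the engineered Ern1 allele stays open for the 3 genes within 10 Mb of Ern1, Lsm12, Arf2 and Med1: if the WT and Xbp1-Ire1 KO libraries carried it and Xbp1 KO did not, these genes would differ in Xbp1 KO alone, and all 3 (against 1 of the 6 farther away) were not called in Xbp1-Ire1 KO against WT and differed back between the knockouts, a test first read in the other direction. Loss of Xbp1 whatever Ern1 does, as the cause for all 9, is argued against by 4 genes that differed back, in divisions redrawn after their results were seen: Lsm12 (1.05 ± 0.13 in cDC1 and 1.34 ± 0.15 in cDC2) and Arf2 (−1.72 ± 0.16 and −1.53 ± 0.21) in both cell types, and Med1 (0.49 ± 0.12) and Supt16 (−1.25 ± 0.30) in cDC1, where for Arf2, cDC2 Xbp1-Ire1 KO vs Xbp1 KO, the call was lost without Xbp1-Ire1 KO replicate 1 or 3 (adjusted p = 0.222 and 0.157) or Xbp1 KO replicate 1 or 2 (0.0813 and 0.0805). An effect of IRE1 that is present in Xbp1 KO and lost in Xbp1-Ire1 KO was not tested for these 4 genes and stays open beside segments. Lsm12 and Med1 are also among the 394 genes weighed in the next paragraph. Of the other 5 genes 3 were called in Xbp1-Ire1 KO against WT. For these 3 and Itgad, loss of Xbp1 cannot be told apart from a segment shared by both knockout lines, though Cox6a2 rose further between the knockouts in cDC1 (3.55 ± 0.29). Mettl17 differed less from WT in Xbp1-Ire1 KO (−0.50 ± 0.54 in cDC1 and −0.75 ± 0.38 in cDC2). Between the knockouts it differed back by 1.72 ± 0.58 and 1.95 ± 0.44 (adjusted p = 0.0682 and 0.474 by edgeR's quasi-likelihood test). As these were not called, Mettl17 stays undecided.

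The 394 genes lowered in cDC1 of Xbp1 KO and raised again in Xbp1-Ire1 KO carried XBP1-like hairpins more often, 37 of 377 with a coding transcript (9.81%) against 358 of 10238 others (3.5%), with an odds ratio of 3.72 (95% interval 2.52 to 5.38, exact p = 4.7e-10) over 10 strata of length. A hairpin here is a CNGCAGN loop (N is any base) closed by 4 perfectly paired bases, sought in the longest protein-coding transcript of each gene. Cleavage by IRE1 at such hairpins may account for part of the 394 genes, such as Ccl22, Notch4 and Srebf2, but Itgb2, Tapbp and Bloc1s1 have 0 such hairpins. Looser hairpins and other transcripts were not searched, so a 0 does not show that a transcript lacks a site for IRE1. The odds ratio was 3.33 (2.23 to 4.85) over 25 strata of length and GC without Xbp1, and 0.252 to 2.88 for the 11 other orders of the loop bases, of which 1 had a lower bound above 1; an earlier single control order, which decided nothing, is among these 11. Length and GC content as the whole cause are argued against by the 289 genes still called both ways after a correction that moved genes by up to 0.673 (median −1.03 before and −0.962 after). The names of the WT libraries cannot be told apart from genotype as a part of the cause: in genes chosen with WT libraries of 1 name and 2 Xbp1 KO libraries, the third Xbp1 KO library differed from WT libraries of the other name by medians of −1.68 to −0.339 over 6 settings, the last for Xbp1 KO replicate 3 against WT replicate 3 (all genes −0.032 to 0.00108), where below −0.5 in each was needed to exclude them, and the test replaced 2 in which libraries or genes served both steps.

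Other splits of the libraries were counted. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. In cDC1, 1 of 10 splits called as many genes in each comparison (1270, 880 and 1437, with 0 the highest other by edgeR's quasi-likelihood test, where 3208, 2558 and 3232 genes had an unadjusted p under 0.05 in the real split). As many lists were called by 2 splits in Xbp1 KO against WT (15, highest other 16), by 1 in Xbp1-Ire1 KO against WT (13, highest other 12) and by 1 between the knockouts (13, highest other 11). The other splits called a median of 8, 7 and 9 lists, so camera at the preset correlation also called lists where genotypes were mixed. Between the cDC2 knockouts 1 of 10 splits called as many genes (4, highest other 1) and 4 as many lists (9, highest other 15, median of the others 7). For cDC2 Xbp1 KO against WT, 1 of 35 splits, the real one, called as many genes (12, highest other 0 by the same test). This share is under 0.05 and is the smallest that 35 splits can give, among many such tests, so chance is less likely but not excluded. Splits also cannot tell genotype from another difference between the mouse lines. As many lists were called by 4 of 35 (12, highest other 14, median of the others 7), so chance is not excluded there. For cDC2 Xbp1-Ire1 KO against WT chance is not excluded for genes (2 of 35 splits, 3 called, highest other 91). Nor is it for lists (18 of 35, 5 called, highest other 9, median of the others 4.5). The split with 91 put the 2 fl-fl WT libraries with Xbp1-Ire1 KO replicate 3 and so points to a structure of the samples by WT name; against the fl-fl libraries 485 genes were called and against the WT-named ones 3. For the interactions chance is not excluded, but the 100 drawn splits cannot decide it. The real counts (264, 272 and 261) were reached by 9, 10 and 10 splits, the real one included (highest other 710, 1083 and 1197). Of these, 9, 9 and 10 kept the cDC1 libraries together in their 2 groups. They carry the difference between the cDC1 genotypes, so they are not free of effects. Splits that mixed cDC1 called at most 68, 453 and 183, of which only 453 exceeded the real count.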

How the results depend on the processing

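The interaction against the WT-named libraries alone was chosen after seeing the data. Among named genes 4849 values under alternatives kept their direction and side of the threshold, 440 lost the call, 4 gained it and 6 reversed; among lists the numbers were 633, 209, 0 and 2. Unless stated, the cause was not tested.

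A fold of at least 2 left 433, 343 and 453 genes in the cDC1 comparisons by construction, in the order Xbp1 KO against WT, Xbp1-Ire1 KO against WT and between the knockouts. Lists called with an estimated correlation were 0, 1 and 1 in cDC1 and 0, 0 and 0 in cDC2, and by fry 7 in cDC1 Xbp1-Ire1 KO and 0, 0 and 0 in cDC2. Fits of the compared groups alone called 828, 575 and 2239 genes in cDC1. The fl-fl WT libraries alone gave 2926 and 1966 genes in cDC1, and 740 genes, 7 lists and 485 genes in cDC2. The WT-named libraries alone gave 345 and 580 genes and 7 lists in cDC1 Xbp1-Ire1 KO, 6 genes in cDC2 Xbp1 KO and 173 for the interaction. DESeq2 called 1356 genes in cDC1 Xbp1-Ire1 KO, 47, 5 and 11 in cDC2 and 432, 462 and 462 for the interactions, and no filter gave 21 in cDC2 Xbp1 KO.

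Reversed, all without a call in the alternative, were N-glycosylation in cDC1 Xbp1-Ire1 KO (adjusted p = 0.918) and, against the same WT-named libraries, list immediate early genes, cDC2 Xbp1-Ire1 KO vs WT (0.495). Ern1, cDC2 Xbp1 KO vs WT, was −0.0154 with a replicate block, −0.053 against fl-fl and −0.00756 to 0.203 with 1 library left out (lowest without cDC2 WT replicate 4). Ern1, cDC2 Xbp1-Ire1 KO vs WT, was 0.0684 against the WT-named libraries and −0.29 to 0.0191 with 1 library left out, above 0 without cDC2 WT replicate 2 (0.0154) or Xbp1-Ire1 KO replicate 2. Xbp1, cDC2 Xbp1 KO vs WT, gained a call with DESeq2 (−1.09, adjusted p = 0.00489), without a filter (−1.08, 0.0393) and against fl-fl (−1.46, 0.001), where Xbp1, cDC2 Xbp1-Ire1 KO vs WT, gained one too (−0.992, 0.0161).

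With 1 library left out, genes ranged over 471 to 2926, 430 to 1966 and 648 to 1297 in cDC1 and 9 to 13, 3 to 4 and 2 to 8 in cDC2. Lists ranged over 14 to 16, 9 to 14 and 12 to 16 in cDC1 and 7 to 16, 3 to 7 and 4 to 11 in cDC2. Overlaps between knockouts were 95 to 1119 the same way and 244 to 1172 back in cDC1, and 3 to 4 and 2 to 6 in cDC2; between cell types they were 5 to 10 and 2 to 3. Interactions ranged over 182 to 418, 170 to 298 and 194 to 261. A replicate block called 1211, 847 and 1376 genes in cDC1, and replicate numbers in the titles did not pair samples within a cell type (18 pairs with the same number, median r 0.00961, threshold 0.1). Description numbers that recur in cDC1 and cDC2 settled nothing: 6 such pairs had r of −0.244 to 0.341 (median 0.0294), and 24 other pairs −0.415 to 0.362. Whether such pairs came from the same mouse is not stated. At these depths and group sizes, simulated 2-fold changes were recovered at 48% to 64% within cell types.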

Other observations

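All tests in this part were chosen after the data were seen. Before any knockout, cDC1 carried more ER folding machinery than cDC2. In WT libraries (n = 3 and 4; CPM here scaled over all 19 libraries) Hspa5 lay at 1980 ± 706 CPM in cDC1 and 794.6 ± 218 in cDC2 (log2 fold change 1.32 ± 0.24 SE), and the disulfide isomerase gene Pdia5 at 307.4 ± 47.9 and 4.27 ± 2.53 CPM (6.17). Of 27 ER chaperones 25 were higher in cDC1 and 0 lower (median 1.21, camera adjusted p = 3.49e-14, and 0.00467 with an estimated correlation), among them Hsp90b1 (1.94), Manf (2.11) and Creld2 (2.34). Xbp1 was higher in cDC1 (178.9 ± 52.8 against 99.16 ± 38.3 CPM; 0.85, adjusted p = 0.00406 by edgeR's quasi-likelihood test) and Ern1 did not pass (25.68 against 25.39 CPM, adjusted p = 0.953).

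MHC class I genes were higher in 14 of 20 with 0 lower (median 0.97, camera adjusted p = 3.53e-06; adjusted p = 0.133 with an estimated correlation), and interferon-stimulated genes were lower in 24 of 37 and higher in 5 (−1.26, adjusted p = 0.000179; adjusted p = 0.41 with an estimated correlation).

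In a scan of 452 windows of 5 Mb for genes with an unadjusted p under 0.05 and the same direction in cDC1 and cDC2 of Xbp1 KO against WT, 1 window passed, and 0 passed for the other 2 comparisons. The window on chromosome 14 from 50 to 55 Mb held 10 of 37 genes against 408 of 10550 in all (Fisher's exact test, adjusted p = 0.000413), among them Dad1, Haus4, Mettl17, Osgep, Pnp, Sall2, Supt16, Tep1 and Tlr11. Tlr11 is also on the cDC1 identity list and Dad1 on the N-glycosylation list. In cDC2, WT libraries of the 2 names (2 against 2) differed in 407 of 11950 genes.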
